A study of Homo sapiens with 17 samples.

How the data were processed

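RNA bound to the LINE-1 proteins ORF1p and ORF2p was measured by RIP-seq, in which a protein is pulled down on affinity media and the RNA that comes with it is sequenced. The cells were N2102Ep, an established human embryonal carcinoma line. The 17 libraries fell into 4 groups by the treatment named in the labels: 4 ORF1p RIP, 4 ORF2p RIP, 3 mock IP and 6 total RNA libraries. The descriptions of the mock IP carry the term mIgG, and no source used here states whether that control matches the antibody of either RIP. Per the labels' protocols, RNA was recovered from the media with TRIzol and phenol-chloroform, DNase was applied before cDNA was made, and libraries came from the Trio RNA-seq kit with probes that remove human ribosomal RNA. Nothing in the labels says that replicates came from separate cultures.

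The authors deposited a single table with 1 line per repeat locus, whose values have the form of expected counts (estimated counts of reads per locus, not scaled to a total). That unit was read from the values, since no source used here names it. Reads were aligned with STAR to hg38, per the submitters' processing notes, which give no version. The program that made the counts is not given in the sources used here, so how reads that match several near-identical copies were shared out is unknown. In each library 68.6% to 86.2% of the values above 0 were whole numbers within a tolerance of 1e-06, as counts with shared reads would be. The table held 3594049 loci of 1080 subfamilies and 45 families in the LINE, SINE, LTR and DNA classes, and 17.5% of the loci were at 0 in all 17 libraries. It held no genes, no satellites and no SVA elements. Of 60 columns of values, 17 matched a labelled sample and were used, and the 43 that matched none entered no step.

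Estimated counts were summed over the loci of each subfamily by name, and 6 subfamilies carried more than 1 family label. Totals ran from 7693841 to 19670774 per library. Values were rounded to whole numbers, subfamilies were filtered with filterByExpr (min.count 10), which left 1074, and libraries were scaled with TMM. The 6 comparisons of group means were tested with edgeR's quasi-likelihood test (edgeR 4.0.16 in R 4.3.3) on all 17 libraries with group as the only term, and p-values were adjusted by Benjamini-Hochberg over all subfamilies tested. A subfamily was called at an adjusted p under 0.05 and a fitted change of at least 2-fold. Every adjusted p given for a subfamily, locus or gene span comes from this test. Standard errors (SE) are the fitted log2 change divided by the square root of its F statistic, and levels are means of CPM (counts scaled to the library total) ± SD on the TMM scale. Each library's share of repeat reads in a class was compared with an exact two-sided permutation test, adjusted over 66 such tests. Overlap of the RIP comparisons was set against 50 simulations in which both RIPs were drawn at the levels of the mock IP.

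The named subfamilies were, in each comparison, the 4 higher and the 4 lower with the largest fitted change among those with an adjusted p under 0.05, at least 4 CPM in 1 group and no overlap between the groups' libraries. The 2 members with the smallest p from each list with 3 or more members tested were added, and L1HS, L1PA2, L1PA3, L1PA4, AluYa5, AluYb8, AluSx, HERVH-int and HERVK-int were named in every comparison. The 10 lists tested were young L1 (L1HS and L1PA2 to L1PA8A), older primate L1 (L1PA10 to L1PA17 and L1PB), mammalian L1 (L1M), AluY, AluS, AluJ, HERVH with its LTR7 ends, HERVK with its LTR5 ends, L2 with MIR, and DNA transposons. Each was tested with limma's camera (limma 3.58.1) at a preset correlation of 0.01 and again with an estimated correlation, and with fry, over 60 tests. The name patterns of the HERVH and HERVK lists also took in unrelated members such as HERVH48-int, LTR70 and LTR57-int, so narrower lists of HERVH-int with LTR7 and of HERVK-int with LTR5 were added after this was seen. The SVA and satellite lists and 16 lists of genes had no member in the table and gave no result. The planned tests of genes, the scaling on genes alone and the shares with genes in the denominator were therefore not run.

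Loci of L1HS, L1PA2 and L1PA3 with at least 10 reads in all were tested singly by the same edgeR test with the library sizes and TMM factors of the subfamily table, and 7568 passed filterByExpr. Comparisons, tests, naming rule, lists and alternatives were fixed, as far as stated so far except for the narrower lists, before the data were examined. A further pair of tests was chosen after the data had been seen. The first covered 30330 loci of every subfamily at a min.count of 100. The other summed the reads of repeat loci that lie within the span of exactly 1 RefSeq gene (GRCh38.p14, 55937 spans), which gave 10431 genes at a min.count of 50. Gene spans come without exons, so whether a locus is exonic or intronic, or on the strand of the gene's transcript, was not used. Starts were moved by 1 to give 1-based hg38 positions.

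On simulated counts drawn from these libraries with 200 subfamilies changed, the subfamily test recovered 95% to 99% of changes of log2 1.5 and 100% of changes of log2 3 across the 6 comparisons, and called 0 to 2 of 874 unchanged subfamilies. The test of young L1 loci recovered 6% to 19% of changes of log2 1.5 and 74% to 81% of changes of log2 3. The test of all loci recovered 6% to 21% and 82% to 86%, and that of gene spans 64% to 67% and 95% to 97%. Counts of single loci therefore miss most changes near the threshold. For loci and gene spans the simulated counts came from the fitted model itself, each feature on its own and with the TMM factors held. Such counts hold no batch and no shift of scale, so they cannot show how often those lead to false calls.

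Alternatives were library totals without TMM, DESeq2 size factors in edgeR, DESeq2 1.42.0 itself, no low-count filter, a min.count of 50, fits with only the groups compared, an adjusted p under 0.01, no minimum fold, a replicate block, and leaving out each library in turn. The descriptions divide the total RNA libraries into series b (replicates 1 and 2) and series bl (replicates 3 to 6), whose meaning is not stated, and each comparison with total RNA was also run within each series. Sample numbers in the descriptions of series bl recur in the ORF2p RIP, while the ORF1p RIP, series b and the mock IP carry other numbers, so there may have been more than 1 run. For the RIP and mock IP groups such a batch and the group cannot be told apart. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 did the remaining steps.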

Results

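The series concerns how cancer cells keep the expression of retrotransposons from provoking an immune response, and the RIP libraries ask which repeat RNAs travel with the LINE-1 (L1) proteins. L1 is the autonomous retrotransposon of the human genome: ORF1p is the RNA-binding protein that coats its transcript, and ORF2p is the endonuclease and reverse transcriptase that copies it. RNA was sequenced from N2102Ep, a human embryonal carcinoma cell line, in 4 ORF1p RIP, 4 ORF2p RIP, 3 mock IP and 6 total RNA libraries. Reads in repeats came to between 7693841 and 9125527 in the ORF1p RIP and 9795032 and 17056092 in the ORF2p RIP. The mock IP had 12703395 to 16271143 and total RNA 8937441 to 19670774. No single locus held more than 1.12% of a library's reads, and no pair of replicates was close enough to be the same library counted again. The p-values below measure only the spread between these libraries, which may be technical.

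Young L1 elements, the L1HS and L1PA subfamilies that arose during ape and monkey evolution, took a larger share of repeat reads in both RIPs than in either control. They made up 10.5% ± 4.37 (SD, n = 4) of reads in the ORF1p RIP and 15.5% ± 0.569 (SD, n = 4) in the ORF2p RIP, with 4.34% ± 0.227 (SD, n = 3) in the mock IP and 4.57% ± 1.39 (SD, n = 6) in total RNA. L1HS, the only L1 subfamily still known to move in humans, made up 2.34% ± 1.3 (SD, n = 4) in the ORF1p RIP and 1.40% ± 0.0581 (SD, n = 4) in the ORF2p RIP, against 0.186% ± 0.00897 (SD, n = 3) in the mock IP. HERVH-int, the internal part of the endogenous retrovirus HERVH that is active in pluripotent cells, and its LTR7 promoters went the other way. They made up 4.51% ± 0.919 (SD, n = 4) in the ORF1p RIP and 6.62% ± 0.514 (SD, n = 4) in the ORF2p RIP against 20.4% ± 0.977 (SD, n = 3) in the mock IP and 10.2% ± 2.23 (SD, n = 6) in total RNA. Alu elements, short repeats that depend on L1 proteins to move, made up 19.2% ± 2.63 (SD, n = 4) in the ORF1p RIP, 12.9% ± 1.58 (SD, n = 4) in the ORF2p RIP and 14% ± 1.25 (SD, n = 3) in the mock IP.

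For young L1, L1HS and HERVH with LTR7, the libraries of each RIP and of the mock IP did not overlap. This gave an exact two-sided permutation p of 0.0571, the smallest that 4 against 3 libraries allow. The adjusted values ran from 0.0524 to 0.943 over the 66 exact permutation tests, so none passed 0.05. L1HS was also higher in every ORF1p RIP library than in every ORF2p RIP library (exact permutation p = 0.0286, adjusted p = 0.0786), while young L1 as a whole was not (exact permutation p = 0.143). These are shares without TMM. On the TMM scale the fitted L1HS change of ORF2p over ORF1p was -0.61, and 0.03 without ORF1p RIP replicate 3. Replicate 3 of the ORF1p RIP stood apart with 17% young L1 where the others held 7.98% to 8.89%. Without it the ORF1p RIP exceeded the mock IP by 3.97 points in place of 6.14. The series of total RNA differed too, with young L1 at 3.01% in series b and 5.35% in series bl, and Alu at 18.4% and 6.86%.

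**Figure D1:**
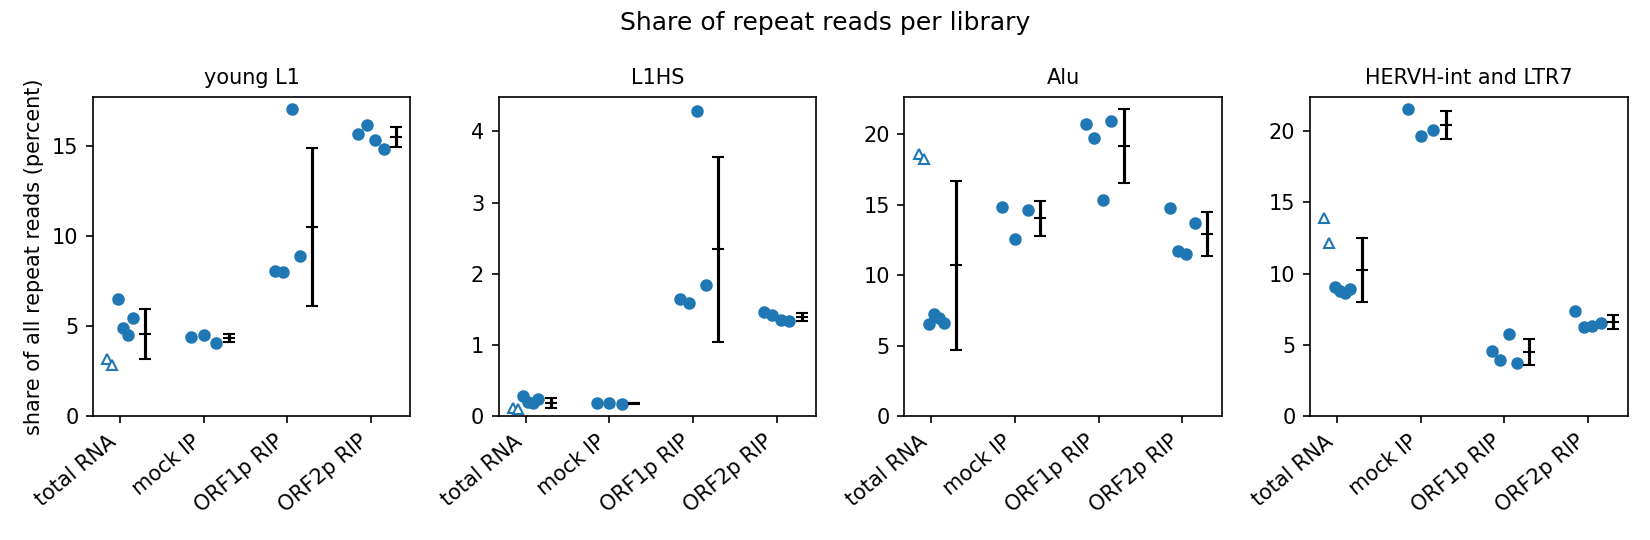
Share of repeat reads (percent) taken by young L1, L1HS, Alu and HERVH-int with LTR7 in each library of the 4 groups, with the black bar at the mean ± SD and open triangles for total RNA of series b. Young L1 and L1HS lie higher in both RIPs than in the mock IP, HERVH-int with LTR7 lies lower, and replicate 3 of the ORF1p RIP holds 17% young L1.

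The ORF1p RIP was set against the mock IP to ask which repeat RNAs came down with ORF1p beyond the background of the pull-down. L1HS RNA was 14.2-fold higher with ORF1p, at 25539.8 ± 18335 CPM (SD, n = 4) against 1793 ± 94.4 CPM (SD, n = 3), a log2 change of 3.83 ± 0.50 (SE, edgeR adjusted p = 8.53e-06). Values were lower in older subfamilies: L1PA2 rose by 2.59 ± 0.45 (SE, edgeR adjusted p = 0.000153) and L1PA3 by 1.37 ± 0.36 (SE, edgeR adjusted p = 0.00437), while L1PA4 at 0.48 ± 0.30 did not pass (SE, edgeR adjusted p = 0.196). The youngest Alu subfamilies rose as well, AluYb8 by 2.27 ± 0.22 (SE, edgeR adjusted p = 3.63e-07) and AluYa5 by 1.66 ± 0.28 (SE, edgeR adjusted p = 0.000122), whereas the older and far more numerous AluSx stood at 0.59 ± 0.33 (SE, edgeR adjusted p = 0.145). HERVK-int, the internal part of the youngest human endogenous retrovirus, rose by 1.19 ± 0.34 (SE, edgeR adjusted p = 0.00875), from 10328 ± 839 CPM (SD, n = 3) to 23504 ± 4319 CPM (SD, n = 4). HERVH-int fell by 2.09 on the log2 scale, from 181985 ± 13074 CPM (SD, n = 3) to 42658 ± 15970.3 CPM (SD, n = 4; edgeR adjusted p = 8.79e-07).

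Of 1074 subfamilies, 79 were higher and 94 lower in the ORF1p RIP than in the mock IP. LTR subfamilies made up most of the lower ones, with 79 lower and 29 higher of 579, and L1 gave 8 higher and 4 lower of 132. The largest rises besides L1HS were those of X5B_LINE at 4.14 ± 0.46 (SE), MER34B-int at 3.92 ± 0.25 (SE) and UCON51 at 3.24 ± 0.24 (SE), with edgeR adjusted p = 2.07e-06, 5.99e-09 and 2.74e-08. Each was the signal of a single locus. Of MER34B-int reads, 91.6% came from chromosome 8 at 100919702 to 100920019, within the span of YWHAZ. Of X5B_LINE reads, 95.6% came from chromosome 12 at 79592550 to 79592618 within that of PAWR, and 84.8% of UCON51 reads came from chromosome 18 at 69843380 to 69843620 within that of DOK6. The largest falls were those of HERV-Fc1-int at -5.82 ± 0.44 (SE, edgeR adjusted p = 3.01e-08), HERV-Fc2-int at -5.08, MLT1E-int at -4.32 and L1P4d at -3.38. Of the HERV-Fc1-int reads of the mock IP, 95% came from a provirus on chromosome 7 at 64835238 to 64839812 within the span of ZNF138. HERV-Fc2-int moved to -8.95 without ORF1p RIP replicate 2 and MLT1E-int to -5.58 without replicate 4, both from a few reads.

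DNA transposons, long extinct elements, rose as a list, with 9 of 94 higher, 0 lower and a median of 0.44 (limma's camera adjusted p = 1.09e-08; adjusted p = 0.894 with an estimated correlation). Charlie16a stood at 1.18 ± 0.08 (SE) and Tigger16b at 1.22 ± 0.10 (SE). The HERVH list fell, with 6 of 15 lower and 1 higher (camera adjusted p = 0.0146; adjusted p = 0.894 with an estimated correlation). Of HERVH-int with LTR7 and its forms alone, 3 of 6 were lower and 1 higher (camera adjusted p = 0.172), and of HERVK-int with LTR5 and its forms alone, 3 of 5 were higher (camera adjusted p = 0.256). Young L1 had 3 of 9 members higher and AluY 5 of 25, and neither list passed (camera adjusted p = 0.226 and 0.0822). In the other lists, mammalian L1 had 3 higher and 2 lower of 88 (camera adjusted p = 0.269), among them L1M6B at 1.37 and L1M3b at -1.09. The broad HERVK list had 4 higher and 1 lower of 20 (camera adjusted p = 0.995), with a median of -0.03 and a mean of 0.15. Older primate L1, AluS, AluJ and L2 with MIR had 0 members past 2-fold (camera adjusted p = 0.769, 0.226, 0.571 and 0.196). In all 60 tests of lists, the members called were as many when adjusted over the list alone as over all subfamilies. In the list of L2 with MIR, remnants shared by all mammals, MIR1_Amn stood at 0.68 and MIR3 at 0.55. By fry, which asks only whether a list moves on balance, this list moved up (adjusted p = 3.96e-07), HERVH-int with LTR7 alone moved down (adjusted p = 0.000841) and HERVK-int with LTR5 alone moved up (adjusted p = 0.000502).

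Replicate 3 of the ORF1p RIP held the highest L1 levels of that group. Without it L1HS stood at 3.19 and L1PA2 at 2.01 over the mock IP, and L1PA3 at 0.87 no longer passed 2-fold. LTR59, at -1.05, missed 2-fold at -0.99 without replicate 2.

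**Figure D2:**
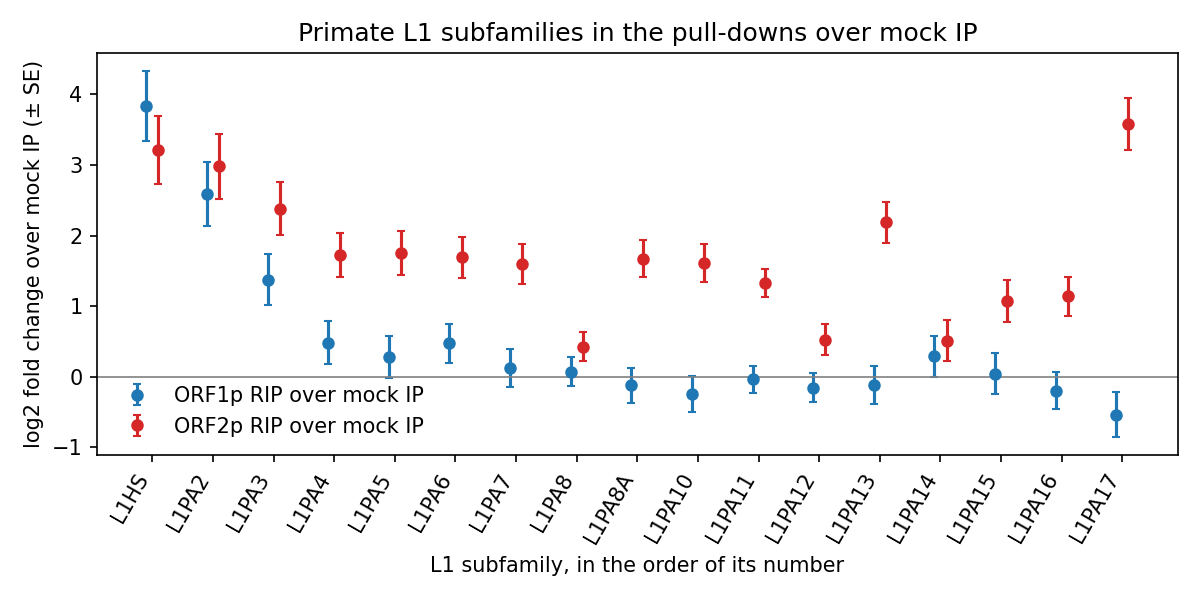
Log2 change over the mock IP (± SE) of L1HS and of L1PA2 to L1PA17 in the ORF1p RIP and the ORF2p RIP. In the ORF1p RIP the change falls from 3.83 in L1HS to 0.48 in L1PA4, and in the ORF2p RIP it stands at 3.22 in L1HS, 1.72 in L1PA4 and 3.58 in L1PA17.

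ORF2p was compared with the mock IP in the same way, and more L1 subfamilies were called higher with it, 40 of 132 against 8. Single loci did not follow this in the test of all loci described below. Of 10538 L1 loci outside young L1, 2706 were higher and 964 lower with ORF2p, and 3175 higher and 4216 lower with ORF1p. L1HS was 9.31-fold higher, at 16682 ± 1025 CPM (SD, n = 4) against 1793 ± 94.4 CPM (SD, n = 3), a log2 change of 3.22 ± 0.48 (SE, edgeR adjusted p = 0.000123). L1PA2 rose by 2.98 ± 0.46 (SE, edgeR adjusted p = 0.000158), L1PA3 by 2.38 ± 0.38 (SE, edgeR adjusted p = 0.000183) and L1PA4 by 1.72 ± 0.32 (SE, edgeR adjusted p = 0.000684). The largest rise was that of L1PA17, an older primate subfamily, at 3.58 ± 0.37 (SE, edgeR adjusted p = 2.87e-06), from 1526 ± 75.9 CPM (SD, n = 3) to 18292 ± 1488 CPM (SD, n = 4). AluYb8 rose by 1.81 and AluYa5 by 1.48 (edgeR adjusted p = 1.13e-05 and 0.000819), while AluSx at 0.20 and HERVK-int at 0.70 did not pass (edgeR adjusted p = 0.672 and 0.122). HERVH-int fell by 1.38 on the log2 scale, to 69937 ± 6046 CPM (SD, n = 4; edgeR adjusted p = 0.000173), below a mock IP that itself held more of it than total RNA, as given below.

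Older L1 subfamilies with large rises drew on few loci. L1M3de at 3.39 ± 0.38 (SE, edgeR adjusted p = 8.57e-06) had 88.2% of its ORF2p RIP reads at chromosome X 73999207 to 73999999, within the span of JPX, a long noncoding RNA. L1ME3C at 3.39 ± 0.43 (SE, edgeR adjusted p = 2.36e-05) had 53.5% at chromosome 2 77096220 to 77098124 within that of LRRTM4. L1PA17 had 49.4% at chromosome 19 21967686 to 21968855 within that of ZNF208, and its leading 5 loci held 89.6%. L1M6B rose by 3.07, L1M2a1 by 2.59 and L1PA13 by 2.19 (edgeR adjusted p = 2.41e-08, 1.44e-08 and 2.97e-05), and LTR58 rose by 1.91 (edgeR adjusted p = 2.12e-06). The falls were smaller than in the ORF1p RIP: LTR6B stood at -1.68, HERVH48-int at -1.34 and LTR81C at -1.32 (edgeR adjusted p = 0.00263, 0.00311 and 0.000237).

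Of 1074 subfamilies, 72 were higher and 16 lower, and 40 of the higher ones were L1, of 132 tested. Without ORF2p RIP replicate 1, 26 were lower. All 3 L1 lists rose, young L1 with 8 of 9 members higher and a median of 1.72 (limma's camera adjusted p = 2.01e-06), and older primate L1 with 8 of 16 and a median of 0.96 (camera adjusted p = 1.53e-05). Mammalian L1 rose with 19 of 88 and a median of 0.50 (camera adjusted p = 5.96e-11). Each of these calls was lost at an adjusted p = 0.894 with an estimated correlation, and the counts were the same adjusted over the list alone. The HERVH list had 3 of 15 lower (camera adjusted p = 0.0246; adjusted p = 0.894 with an estimated correlation), and HERVH-int with LTR7 alone 2 of 6 (camera adjusted p = 0.133). AluY had 3 of 25 higher, HERVK 1 of 20 and DNA transposons 5 of 94, among them Tigger16b at 1.26 and Charlie10 at 1.01. These lists did not pass (camera adjusted p = 0.196, 0.278 and 0.0822). AluS, AluJ and L2 with MIR did not either, with 0 members past 2-fold (camera adjusted p = 0.534, 0.845 and 0.39). The medians of AluY at 0.21, AluS at 0.27 and DNA transposons at 0.09 turned to -0.09, -0.03 and -0.22 with library totals. By fry, L2 with MIR, the broad HERVK list and HERVH-int with LTR7 alone moved down (adjusted p = 0.00148, 0.0253 and 0.00506).

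Scaling mattered in this comparison. With library totals in place of TMM the median of all subfamilies moved to -0.34, and 43 subfamilies were higher and 64 lower, 40.2% higher in place of 81.8%. The L1 subfamilies named in this comparison stayed above 2-fold with library totals, and Tigger16b at 0.95 and Charlie10 at 0.70 did not. Over the 1074 subfamilies, which are not independent replicates, the changes with ORF2p correlated with the difference of series bl from series b of total RNA (Pearson 0.469, Spearman 0.493), more than those with ORF1p did (0.215 and 0.223). Charlie10 also missed 2-fold at 0.99 without total RNA replicate 3 and under other settings.

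In both RIPs 17 of the same subfamilies were higher than in the mock IP, and 10 with library totals, where independent lists of 79 and 72 would share 5.3. They included 6 of L1, namely L1HS, L1PA2, L1PA3, L1P1, L1M3de and L1M6B, and AluYa5, AluYb8 and AluYc3, young Alu subfamilies. Another 5 were lower in both, where independent lists would share 1.4. Both comparisons used the same 3 mock IP libraries, which are too few to divide, so part of the excess may come from the shared controls. In 50 simulations with no change, which gave almost no calls, 0 were shared. When the 79 and 72 with the smallest p among those higher were taken instead, a step added after the result was seen, they shared 27.4 on average (19 to 37). Those ranks passed no threshold, so they are not the same measure as the 17 called. The count of 17 alone therefore does not settle whether an effect is shared.

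Between the RIPs, L1HS did not pass by edgeR, at -0.61 ± 0.39 for ORF2p over ORF1p (SE, adjusted p = 0.195), and it stood at 0.03 without ORF1p RIP replicate 3. Some older L1 subfamilies were higher with ORF2p. L1PA4 stood at 1.24 ± 0.28 (SE, edgeR adjusted p = 0.00142), and L1PA7 at 1.47 ± 0.25 (SE, edgeR adjusted p = 0.000132). L1PA8A stood at 1.79 ± 0.24 (SE, edgeR adjusted p = 7.95e-06), L1PA13 at 2.30 ± 0.26 (SE, edgeR adjusted p = 1.46e-06) and L1PA17 at 4.12 ± 0.34 (SE, edgeR adjusted p = 4.3e-08). HERV-Fc1-int at 4.56, MLT1E-int at 4.36 and L1P4d at 4.06 were higher with ORF2p as well (edgeR adjusted p = 1.66e-07, 3.3e-06 and 9.52e-11), and MLT1E-int stood at 5.62 without ORF1p RIP replicate 4. UCON51 at -3.62, MER34B-int at -3.16, MLT1E3-int at -3.05 and LTR35 at -2.57 were lower (edgeR adjusted p = 3.67e-09, 4.58e-09, 3.63e-10 and 7.38e-09), as was AluYh7 at -1.97 (edgeR adjusted p = 1.29e-05). L1PA2 at 0.39, AluSx at -0.39 and HERVK-int at -0.48 did not pass (edgeR adjusted p = 0.398, 0.283 and 0.195).

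In counts, 133 subfamilies were higher and 70 lower with ORF2p than with ORF1p, among them 39 L1 higher and 1 lower. Older primate L1 had 9 of 16 members higher (limma's camera adjusted p = 0.00158) and mammalian L1 19 of 88 with 1 lower (camera adjusted p = 0.00273), and both calls were lost at an adjusted p = 0.894 with an estimated correlation. Young L1 had 6 of 9 higher and did not pass (camera adjusted p = 0.0803). DNA transposons were lower, with 6 of 94 lower and 1 higher (camera adjusted p = 4.14e-05; adjusted p = 0.894 with an estimated correlation), as in Charlie17a at -1.08. The HERVH list had 5 higher and 2 lower of 15, with LTR70 at 1.71 and LTR7C at -1.73 (camera adjusted p = 0.437). HERVK had 1 higher and 4 lower of 20, AluY 1 lower of 25, and AluS, AluJ and L2 with MIR 0 past 2-fold (camera adjusted p = 0.453, 0.437, 0.437, 0.516 and 0.0568). By fry, young L1 and HERVH moved up (adjusted p = 0.00896 and 0.0482), and HERVK, L2 with MIR and HERVK-int with LTR5 alone moved down (adjusted p = 0.0235, 3.53e-09 and 0.000457). L1PA3 at 1.01 (edgeR adjusted p = 0.0142) missed 2-fold with library totals at 0.86 and without ORF1p RIP replicate 1, 2 or 4 or ORF2p RIP replicate 2. It stood at 1.51 without ORF1p RIP replicate 3, where HERVH-int moved from 0.71 to 1.01. With library totals the median moved to -0.25 and 95 subfamilies were higher and 115 lower, 45.2% higher in place of 65.5%.

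Total RNA served as the other reference, for what the cells contained. L1HS was 14.9-fold higher in the ORF1p RIP than in total RNA, a log2 change of 3.90 ± 0.37 (SE, edgeR adjusted p = 2.44e-07), and 9.75-fold higher in the ORF2p RIP, a change of 3.29 ± 0.37 (SE, edgeR adjusted p = 4.56e-06), over 1710.3 ± 731 CPM (SD, n = 6) in total RNA. L1PA2 stood at 2.56 and 2.95 (edgeR adjusted p = 1.06e-05 and 8.51e-06). AluYb8 stood at 2.38 in the ORF1p RIP and 1.93 in the ORF2p RIP (edgeR adjusted p = 7.41e-09 and 2.77e-07). L1PA17 was higher in the ORF2p RIP at 3.02 ± 0.27 (SE, edgeR adjusted p = 4.17e-07) and lower in the ORF1p RIP at -1.10 ± 0.28 (SE, edgeR adjusted p = 0.00314). LTR5_Hs, the promoter of the youngest HERVK, was higher in the ORF1p RIP at 2.23 ± 0.22 (SE, edgeR adjusted p = 3.51e-07), while HERVK-int itself stood at 0.17 ± 0.28 (SE, edgeR adjusted p = 0.616), with 1.25 over total RNA of series b and -0.21 over series bl. HERVH-int at -0.98 in the ORF1p RIP was just under 2-fold lower (edgeR adjusted p = 0.000318), and at -0.26 in the ORF2p RIP it did not pass (edgeR adjusted p = 0.275).

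Over total RNA, the ORF1p RIP had 98 subfamilies higher and 89 lower and the ORF2p RIP 55 higher and 14 lower, with 9 lower without ORF2p RIP replicate 4. In the ORF1p RIP the Alu lists rose, AluY with 12 of 25 higher (limma's camera adjusted p = 0.000299), AluS with 13 of 17 (camera adjusted p = 0.00384), and DNA transposons rose with 8 of 94 (camera adjusted p = 0.000156). These calls were lost at an adjusted p = 0.894 with an estimated correlation. AluJ had 0 of 4 higher (camera adjusted p = 0.196). Young L1 had 3 of 9 higher, older primate L1 2 of 16 lower and mammalian L1 1 higher and 6 lower of 88, and none passed (camera adjusted p = 0.192, 0.303 and 0.156). Nor did HERVH with 2 higher and 3 lower of 15, HERVK with 4 higher and 1 lower of 20, and L2 with MIR with 0 past 2-fold (camera adjusted p = 0.213, 0.727 and 0.0822). In the ORF2p RIP the L1 lists rose, young L1 with 8 of 9 (camera adjusted p = 6.37e-08), and older primate L1 with 6 of 16 (camera adjusted p = 0.000348; adjusted p = 0.894 for both with an estimated correlation). Mammalian L1 rose with 8 higher and 1 lower of 88 (camera adjusted p = 0.0134; adjusted p = 0.894 with an estimated correlation) and a median of 0.09 that turned to -0.31 with library totals. AluY rose there with 8 of 25 and AluS with 1 of 17 (camera adjusted p = 6.08e-05 and 0.00374; adjusted p = 0.894 for both with an estimated correlation). AluJ, HERVH, HERVK, L2 with MIR and DNA transposons did not pass, with 0, 0, 1, 0 and 3 higher (camera adjusted p = 0.375, 0.437, 0.516, 0.637 and 0.437). By fry, young L1, AluJ, L2 with MIR and HERVK-int with LTR5 alone also moved up in the ORF1p RIP (adjusted p = 0.0359, 0.00474, 3.53e-09 and 2.44e-06) and HERVH moved down (adjusted p = 0.00865), while mammalian L1 in the ORF2p RIP did not pass (adjusted p = 0.166).

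The largest other changes over total RNA were, in the ORF1p RIP, UCON51 at 3.69, MER34B-int at 3.23, X5B_LINE at 2.79, HERV-Fc1-int at -4.31, MLT1E-int at -4.29, LTR7A at -3.80 and L1P4d at -3.45 (edgeR adjusted p between 2.21e-10 and 3.12e-06). In the ORF2p RIP they were LTR22A at 2.96, with 93.3% of its reads at chromosome 4 19063768 to 19064234, and MER133A at -1.80, HERVK11D-int at -1.31, HERV1_LTRd at -1.24 and MER83C at -1.08 (edgeR adjusted p between 7.81e-10 and 0.00111). L1PA3 in the ORF1p RIP stood at 1.45, and at 0.95 without replicate 3, where L1HS stood at 3.26 and L1PA2 at 1.98. MLT1E-int stood at -5.55 without ORF1p RIP replicate 4, and MER83C at -0.96 without total RNA replicate 2. AluSx in the ORF1p RIP, at 1.09, lost its call without total RNA replicate 3 at 0.95 or replicate 6 at 0.99, and L1PA17 lost its own at -0.96 without total RNA replicate 3.

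The series of total RNA entered these values. With series b alone as the reference, AluSx in the ORF1p RIP stood at 0.29, AluSx1 at 0.44, AluSg7 at 0.46 and L1PA17 at -0.07, and these lost their calls. HERVK-int at 1.25 and HERVH-int at -1.29 in the ORF1p RIP gained calls there (edgeR adjusted p = 3.92e-07 and 3.48e-05). L1HS kept its call over either series, at 4.75 over series b and 3.53 over series bl in the ORF1p RIP and at 4.20 and 2.97 in the ORF2p RIP. In the ORF2p RIP AluSg, at 1.23 over all total RNA, stood at 0.37 over series b and lost its call, and AluSx stood at -0.07 over series b and 1.29 over series bl, where it was called. Counts were 89 higher and 30 lower in the ORF2p RIP over series b alone and 96 higher and 25 lower over series bl alone. With library totals the median moved to -0.20 in the ORF1p RIP, with 55 higher and 127 lower (30.2% higher in place of 52.4%), and to -0.47 in the ORF2p RIP, with 30 higher and 77 lower (28% in place of 79.7%).

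The mock IP was set against total RNA to ask what differed without an antibody to either L1 protein, and HERVH RNA was among the few repeats called. HERVH-int was higher in the mock IP at 1.12 ± 0.19 (SE, edgeR adjusted p = 0.00391), with 181985 ± 13074 CPM (SD, n = 3) against 83868 ± 12862 CPM (SD, n = 6). Its promoters LTR7 at 1.45 ± 0.24 (SE, edgeR adjusted p = 0.00391) and LTR7Y at 1.41 ± 0.24 (SE, edgeR adjusted p = 0.00391) were higher too, as were HERV-Fc1_LTR1 at 2.04, HERV-Fc1-int at 1.51 and HERVFH21-int at 1.44 (edgeR adjusted p = 0.0183, 0.0135 and 0.0498). L1HS at 0.07 ± 0.39 (SE, edgeR adjusted p = 0.907), L1PA2 at -0.03 ± 0.38 (SE, edgeR adjusted p = 0.956), AluSx at 0.51 ± 0.29 (SE, edgeR adjusted p = 0.226) and HERVK-int at -1.01 ± 0.32 (SE, edgeR adjusted p = 0.0911) did not pass. Both of the last changed with the series: AluSx stood at -0.25 over series b and 1.11 over series bl, and HERVK-int at 0.12 and -1.35, and both were called over series bl (edgeR adjusted p = 5.5e-08 and 3.48e-08).

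In all, 8 subfamilies were higher and 0 lower by edgeR, with 310 at an unadjusted p under 0.05, and DESeq2 called 5 lower. Without total RNA replicate 1, 21 were higher and 14 lower, and without replicate 2, 19 and 14. The higher count was 5 without total RNA replicate 3 or 4 and 4 without mock IP replicate 1 or 3. The lowest values that passed the test, MER57C1 at -0.73, HERV1_LTRd at -0.71, MER101 at -0.55 and LTR70 at -0.47, were under 2-fold (edgeR adjusted p between 0.00464 and 0.0223). The HERVH list rose with 3 of 15 higher (limma's camera adjusted p = 0.00476; adjusted p = 0.894 with an estimated correlation), and HERVH-int with LTR7 alone with 3 of 6 (camera adjusted p = 0.000295; adjusted p = 0.255 with an estimated correlation). By camera, AluY, AluS and AluJ moved up (adjusted p = 2.06e-05, 6.4e-05 and 0.048) and mammalian L1 and DNA transposons moved down (adjusted p = 5.33e-13 and 1.51e-06), all with 0 members past 2-fold and all at an adjusted p = 0.894 with an estimated correlation. By fry none of these 5 passed (adjusted p = 0.0876, 0.101, 0.0876, 0.119 and 0.164), and L2 with MIR moved up (adjusted p = 0.00923). Members of AluS and AluJ turned with the series, with AluSx1 at -0.17, AluSc8 at -0.18, AluJr4 at -0.13 and AluJr at -0.14 over series b and at 1.33, 1.25, 0.88 and 0.98 over series bl. Young L1, older primate L1, HERVK and L2 with MIR did not pass, with 0 members past 2-fold (camera adjusted p = 0.845, 0.0803, 0.39 and 0.4), and young L1 had a median of -0.02 with a mean of 0.01.

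These calls were fragile. With series b alone as the reference, HERVH-int stood at 0.86, LTR7 at 0.87, LTR7Y at 0.81 and HERV-Fc1-int at 0.78, and none kept its call. With library totals the median moved to -0.13, HERVH-int to 0.99, and 7 were higher and 10 lower (41.2% higher in place of 100%). HERV-Fc1-int lost its call without mock IP replicate 1 at 1.37 and without replicate 3. HERV-Fc1_LTR1 lost its own without replicate 1 at 1.70, replicate 3, or total RNA replicate 3 or 4. HERVFH21-int lost its own without any library other than total RNA replicate 1 or 2, reaching 1.29 without total RNA replicate 4.

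Single loci of the youngest L1 subfamilies were then tested, to see how many of those with enough reads were higher. Of 7568 loci of L1HS, L1PA2 and L1PA3, 4520 were higher and 305 lower in the ORF1p RIP than in the mock IP, and 5937 were higher and 69 lower in the ORF2p RIP. Among L1HS loci 834 of 977 (85.4%) were higher with ORF1p and 867 (88.7%) with ORF2p, while among L1PA3 loci it was 48.8% and 72.5%. The 977 are those of 1585 L1HS loci that passed the filter, and a locus can pass because it is high in a RIP. Reads may also have been divided between near-identical copies. These shares therefore cannot show how widely the rise was spread over the genome. Of 309 full-length L1HS loci over 5.9 kb 298 were higher with ORF1p and 303 with ORF2p, and of 215 L1HS loci under 1 kb 159 and 161 were, though short loci hold fewer reads and the difference was not tested. Full-length loci held 76.6% ± 0.904 (SD, n = 4) of L1HS reads in the ORF1p RIP, 65.8% ± 2.22 (SD, n = 4) in the ORF2p RIP, 58.9% ± 1.07 (SD, n = 3) in the mock IP and 56.2% ± 2.00 (SD, n = 6) in total RNA. Over total RNA, 5487 young loci were higher and 281 lower in the ORF1p RIP and 6564 higher and 62 lower in the ORF2p RIP. The mock IP had 41 higher and 0 lower by edgeR, with 806 at an unadjusted p under 0.05, and DESeq2 was not run on loci. That count of 41 was 5 without mock IP replicate 2 and 8 without replicate 1. It was 18, 7, 7 and 10 without total RNA replicate 1, 4, 5 and 6, and 25 and 19 without ORF2p RIP replicate 2 and 4. Without ORF1p RIP replicate 3, 63 were higher and 1 lower.

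The L1HS copy on chromosome 22 at 28663284 to 28669315, on the plus strand within the span of TTC28, held 10.4% of all L1HS reads in the ORF1p RIP. It stood at 2640 ± 1850 CPM (SD, n = 4) with ORF1p, 102.3 ± 13.3 CPM (SD, n = 4) with ORF2p and 7.50 ± 1.13 CPM (SD, n = 3) in the mock IP. It was higher by 8.46 ± 0.81 with ORF1p (SE, edgeR adjusted p = 8.96e-09) and by 3.77 ± 0.64 with ORF2p (SE, edgeR adjusted p = 2.85e-05). The difference between the RIPs was -4.69 ± 0.59 (SE, edgeR adjusted p = 1.35e-06). Without ORF1p RIP replicate 3 the first and last of these were 7.84 and -4.07. A copy on chromosome 1 at 239623499 to 239629523, within the spans of CHRM3 and LOC105373225, was higher by 6.52 with ORF1p and 2.17 with ORF2p, a difference of -4.35 (edgeR adjusted p = 2.72e-07), and without ORF1p RIP replicate 3 these were 5.93 with ORF1p and -3.75 for the difference. A copy on chromosome 7 at 25041861 to 25047891 was higher by 7.03 with ORF1p and 4.09 with ORF2p (edgeR adjusted p = 8.06e-09 for ORF1p), and a copy on chromosome 12 at 74874869 to 74880901 by 6.37 and 3.41 (edgeR adjusted p = 2.11e-08 for ORF1p). The other of the 5 L1HS loci with the most reads, a shorter copy on chromosome 3 at 26728189 to 26730137, did not show this. It stood at 441.3 ± 583 CPM (SD, n = 4) with ORF1p and 604.3 ± 261 CPM (SD, n = 4) with ORF2p, a difference of 0.45 (edgeR adjusted p = 0.73) that was 2.01 without ORF1p RIP replicate 3. The 5 loci were picked by mean CPM over all libraries, and for all but the shorter copy the ORF1p RIP held by far the highest level. That pick favours copies high with ORF1p, so these 5 do not stand for L1HS loci at large. Between the RIPs, 58 of 977 L1HS loci were higher and 86 lower with ORF2p, against 875 and 144 of 4358 L1PA3 loci. The median changes of ORF2p over ORF1p were -0.13 and 0.82. Over all young loci 1342 were higher and 305 lower, and the higher count ran from 881 without ORF1p RIP replicate 1 to 2889 without replicate 3. How the counting divided reads that fit several near-identical copies is not given in the sources used here, so the values of single L1HS loci are uncertain.

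**Figure D3:**
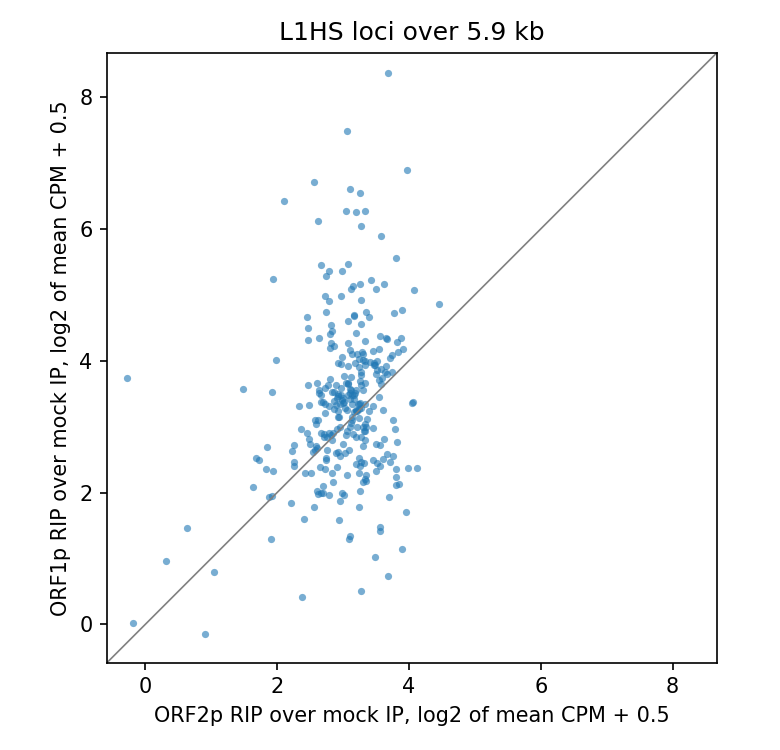
Log2 ratio over the mock IP of 305 full-length L1HS loci (over 5.9 kb; those on chromosome Y are left out of the 309), ORF1p RIP against ORF2p RIP, from mean CPM plus 0.5, with the grey line where both are equal. Ratios reach 8.37 with ORF1p and 4.45 with ORF2p, around medians of 3.34 and 3.11.

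A test of 30330 loci of every subfamily, chosen after the data were seen, gave 11831 loci higher and 11846 lower in the ORF1p RIP than in the mock IP, and 9229 higher and 4609 lower in the ORF2p RIP. HERVH-int loci accounted for many of the lower ones: of 1940, 1697 were lower with ORF1p and 1533 with ORF2p. Among them was a copy within the span of LINC-ROR, a long noncoding RNA of pluripotent cells, on chromosome 18 at 57065100 to 57068321. It stood at 2.07 ± 0.428 CPM (SD, n = 4) with ORF1p against 309.8 ± 14 CPM (SD, n = 3) in the mock IP (edgeR log2 change -7.23 ± 0.37 SE, adjusted p = 1.93e-11). Of the 1940, 103 were higher with ORF1p than in the mock IP, and 5 with ORF2p. The mock IP itself held more HERVH-int than total RNA, and this test of loci was not run over total RNA. Over total RNA, of the 6 subfamilies of HERVH-int with LTR7, 0 were lower and 0 higher with ORF2p. Their median there was -0.01, and -0.44 with library totals. With ORF1p, 1 was lower and 2 were higher. A fall below the mock IP is thus not by itself a fall below what the cells contained. A HERVH-int copy on chromosome 15 at 35239063 to 35242176, within the span of DPH6, differed between the RIPs. It stood at 4264 ± 1520 CPM (SD, n = 4) with ORF1p and 27.96 ± 4.33 CPM (SD, n = 4) with ORF2p (edgeR log2 change of ORF2p over ORF1p -7.25 ± 0.35 SE, adjusted p = 1.87e-11). For a ranking between the RIPs, loci had to pass the test without overlap, with at least 16 CPM in 1 group. They also needed 10 reads in each library of both, and those on chromosome Y were left out. Among the ranked loci the L1PA17 pair within the span of ZNF208 differed most, at 9.65 and 9.19 for ORF2p over ORF1p. The copy on chromosome 19 at 21966117 to 21967442 stood at 6929 ± 566 CPM (SD, n = 4) with ORF2p and 8.62 ± 1.05 CPM (SD, n = 4) with ORF1p (edgeR log2 change 9.65 ± 0.68 SE, adjusted p = 4.41e-10). Of the loci tested between the RIPs, 14196 were higher and 8808 lower with ORF2p.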

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

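The test of library size, the pick of loci by total RNA, the comparison of shares by distance with its bounds, and all splits of the samples were chosen only after the results were seen. The intervals on the other tests below were added after their values were known, which changed no reading. Every interval in this section was made by resampling loci or subfamilies, never libraries. Loci and subfamilies are not independent replicates, so the intervals do not measure the spread between libraries.

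Replicate 3 of the ORF1p RIP lay far from the other 3 in 12 measures. Chance alone puts about 1 in 20 groups in this list, about 3.5 of the 69 groups examined. The 12 overlap, since L1HS is part of young L1, L1 and LINE, and a rise in 1 share lowers others. They are therefore not separate departures. It held 17% young L1 (the others 7.98% to 8.89%), 4.28% L1HS (1.60% to 1.85%), 43.2% L1 (31.7% to 33.0%) and 51.9% LINE (41.7% to 43.1%), and less of SINE at 21.7% (27.9% to 29.1%) and of L2 with MIR at 13.3% (15.9% to 16.1%). L1HS stood at 53009 CPM (15472 to 17613), L1PA2 at 67904 (21342 to 24689), L1PA3 at 39500 (14485 to 15382) and L1PA4 at 15550 (6868 to 7162). Reads fell on 636018 loci where the others covered 971567 to 1026240, and the 100 most counted loci took 10.4% (7.21% to 7.64%).

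A wrong label was argued against for this library, which correlated with the other 3 more closely than with any other group by 0.0365 (95% interval 0.0301 to 0.0424), and so was a small library, since its total was 91.2% of their mean. A candidate explanation is less unbound background in that pull-down, which would raise most what ORF1p enriched. Over 986 subfamilies its ratio to the other 3 rose with theirs over the mock IP at a Spearman rho of 0.219 (95% interval 0.155 to 0.282), against -0.298, -0.169 and -0.434 when the other replicates were treated alike, and a rho of 0.5 had been set for the explanation and 0.2 against it, so it stays open. Less background would also be expected to lower what the mock IP is rich in. SINE and L2 with MIR fell in replicate 3, but HERVH-int with LTR7, at 19.6% to 21.5% in the mock IP libraries, did not. It held 5.78% in replicate 3 and 3.72% to 4.55% in the other 3. The labels give no biological difference between these replicates, and none was tested.

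Full-length L1HS loci differed more from each other with ORF1p than with ORF2p, with interquartile ranges of 1.36 and 0.58 in the log2 ratio over the mock IP, which are 2.35 as a ratio (95% interval 1.89 to 2.82). A single library was argued against, as the ratio was 2.22 (1.78 to 2.64) without ORF1p RIP replicate 3, and so were loci with few reads, as it was 2.53 (1.94 to 3.27) over the 155 loci at or above the median level in total RNA, while 3.01 (1.97 to 4.08) over the 116 loci of at least 50 CPM in either RIP decides nothing, since that filter acts on the ratio itself. Reads divided between near-identical copies could even out the ORF2p values and stay open: the older and more distinct full-length L1PA4 to L1PA8A gave a ratio of 0.992 (0.928 to 1.06), where this explanation needed 1.1 or less, with L1PA2 at 1.60 and L1PA3 at 1.12 between. From L1HS through L1PA2 and L1PA3 to these older loci the ORF2p range rose, at 0.58, 0.785, 1.0 and 1.33, while the ORF1p range was 1.36, 1.26, 1.12 and 1.32, and why sharing would even out the ORF2p values alone was not tested. An interquartile range of ORF1p values that is wide in L1HS alone was thus not seen. This range leaves out the tails, so it cannot show whether ORF1p stayed with the RNA of the few loci that encode it. Outside chromosome Y the highest log2 ratios of full-length L1HS loci were 8.37 with ORF1p and 4.45 with ORF2p. That explanation and other biological ones stay open, untested.

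Outside young L1, 6260 of 26396 repeat loci were higher in the ORF2p RIP than in the mock IP, and L1 made up 43.2% of these loci and 38.9% of the others. Read-through from full-length young L1 into its flanks was argued against as the whole cause: 27.2% of the 712 loci within 5 kb of such an element were higher and 23.6% of those beyond, which is 86.7% of the first share (95% interval 77.5% to 98.3%), with 23.7% of the 20745 loci beyond 50 kb. It stays open for the 194 higher loci within 5 kb, where the excess was 3.63 percentage points (0.364 to 7.0), and these were 3.10% of the higher loci (2.70% to 3.56%), a share that decides nothing alone, as it could not have passed 11.4%. RNA that also differs between the series of total RNA may contribute: the median log2 ratio of series bl over series b was higher at these 6260 loci than at the others by 0.210 (0.170 to 0.251), where 1 or more had been set for the explanation and 0.2 or less against it. Whether the mock IP matches the ORF2p antibody could not be tested, and binding by ORF2p stays among the open explanations. With ORF1p, 9358 of the same 26396 loci were higher than in the mock IP, and 3191 were higher in both RIPs. A rise at loci outside young L1 was therefore not particular to ORF2p.

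HERVH-int in ORF2p RIP replicate 1 stood at 78985 CPM, above 66467 to 67477 in the other 3. ERV24_Prim-int was lower with ORF1p and higher with ORF2p than in the mock IP, at -1.43 and 1.0, a difference of 2.43 (edgeR adjusted p = 3e-08). FordPrefect stood at -1.06 and 1.20, a difference of 2.25 (edgeR adjusted p = 8.28e-13). MLT1E1-int stood at -1.96 and 1.65, a difference of 3.61 (edgeR adjusted p = 5.7e-06).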

How the results depend on the processing

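The series settings and replicate block for young L1 loci, every setting for all loci and for gene spans, and the narrower lists were chosen only after the results were seen. Across 109 main values and 1146 alternatives, 107 left their side of the threshold or moved by over 1.5 times. No called value changed direction, but counts have no direction, and list tests with an estimated correlation were not checked for it. The balance of counts did turn with library totals, as ORF2p RIP over mock IP went from 72 higher and 16 lower to 43 and 64. Values under the threshold did turn, as L1HS in mock IP over total RNA and the AluJ list in ORF2p RIP over mock IP did with library totals. Of 60 list tests 29 passed by fry, 17 of them among the 23 by camera. L1HS kept its rise over the mock IP and over total RNA under each alternative run. Among single named subfamilies 4963 values under alternatives stayed on their side of the threshold, 72 weakened, 41 strengthened and 0 called ones changed direction, and among shares with a library left out 413 stayed, 89 weakened and 8 strengthened. The cause was not tested except where the setting itself shows it.

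With library totals in place of TMM, counts were 43 higher and 64 lower for ORF2p RIP over mock IP, 55 higher for ORF1p RIP over total RNA, 30 and 77 for ORF2p RIP over total RNA, 10 lower for mock IP over total RNA, and 115 lower for ORF2p over ORF1p RIP, with 10 higher in both RIPs. Young loci then gave 134 lower for ORF2p RIP over mock IP and 116 over total RNA, and gene spans 1859 lower for ORF2p RIP over mock IP. Of 60 list tests, the 23 camera calls all ended at an adjusted p of 0.894 with an estimated correlation. Library totals ended 0 of them and added 5 (camera adjusted p = 0.0347 for AluY in ORF2p RIP over mock IP, 0.0388 for young L1 in ORF1p RIP over total RNA, 0.0203 for DNA transposons in ORF2p RIP over total RNA, and 0.00541 for young L1 and 0.0383 for L2 with MIR in ORF2p over ORF1p RIP). DESeq2 called 5 lower in mock IP over total RNA.

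A min.count of 50 tests fewer loci, and left 7 subfamilies lower in ORF2p RIP over total RNA. Young loci then gave 2951 higher and 110 lower (ORF1p over mock), 3480 and 16 (ORF2p over mock), 3042 and 118 (ORF1p over total RNA), 3539 and 15 (ORF2p over total RNA), 5 higher (mock over total RNA), and 890 and 203 (ORF2p over ORF1p). For all loci a min.count of 50 tests more, and gave 24682 and 24941, 15538 and 10139, and 27985 and 21364 for the RIPs over mock IP and for ORF2p over ORF1p. Without a minimum fold counts were 279 and 275, 179 and 167, 313 and 307, 193 and 221, 24 and 7, and 302 and 304 in the order of the report's comparisons (ORF1p and ORF2p over mock, ORF1p and ORF2p over total RNA, mock over total RNA, ORF2p over ORF1p), with 63 higher in both RIPs. In mock IP over total RNA, 4 were higher at an adjusted p under 0.01. With only these groups fitted, at an adjusted p under 0.05, 1 was higher.

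Total RNA of series b alone gave 89 higher and 30 lower for ORF2p RIP and 1 higher for mock IP, with 28 young loci lower for ORF2p RIP, and series bl alone gave 96 and 25 for ORF2p RIP and 80 and 19 for mock IP, with 3 young loci lower for mock IP. Same-numbered libraries showed no steady sign of pairing: 12 of 21 pairs by title number correlated above 0.1, from -0.502 to 0.491, and 11 of 26 by description number. No pairs of unlike numbers are set beside these values, so pairing is not excluded. With title number as a replicate block, mock IP over total RNA gave 4 higher, and young loci 38 lower for ORF2p RIP and 1 higher for mock IP over total RNA.

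Leaving out each library in turn gave 13 to 26 lower in ORF2p RIP over mock IP (26 without ORF2p RIP replicate 1) and 9 to 15 lower in ORF2p RIP over total RNA (9 without ORF2p RIP replicate 4). It gave 4 to 21 higher and 0 to 14 lower in mock IP over total RNA (4 without mock IP replicate 1, 21 and 14 without total RNA replicate 1). Young loci in mock IP over total RNA ran from 5 higher without mock IP replicate 2 to 63 without ORF1p RIP replicate 3, with 0 to 1 lower, and in ORF2p over ORF1p RIP from 881 higher without ORF1p RIP replicate 1 to 2889 without replicate 3. Planned tests of genes, scaling on genes alone and shares with genes in the denominator were not run, as the table holds no genes. Simulated changes of log2 1.5 were recovered less often at single loci than in gene spans or subfamilies.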

Other observations

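All tests of gene spans and of splits reported here were chosen only after the results were seen, and the genes named were picked, after their values were known, from pluripotency and noncoding RNA lists fixed earlier. Repeat reads within the spans of 20 pluripotency genes gave 15 lower and 3 higher with ORF1p and 3 of each with ORF2p, and those of 10 noncoding RNA genes 2 lower and 5 higher with ORF1p and 3 higher with ORF2p. The 3 pluripotency spans lower with ORF2p depended on the scaling, as 9 were lower with library totals, and on single libraries, as 1 was lower without mock IP replicate 1 and 4 without ORF2p RIP replicate 4. With ORF1p, 13 to 15 were lower under every alternative. Of the noncoding RNA spans, 2 were higher and 1 lower with ORF2p with library totals, and 4 to 5 were higher with ORF1p. L1TD1, a domesticated L1 ORF1p gene of pluripotent cells, and TERF1, a telomere-binding protein, had repeat reads within their spans that were lower with ORF1p and higher with ORF2p than in the mock IP. L1TD1 stood at 56.8 ± 32.3 CPM (SD, n = 4) with ORF1p, 4427 ± 178 CPM (SD, n = 4) with ORF2p and 459.8 ± 6.24 CPM (SD, n = 3) in the mock IP, changes of -3.02 ± 0.43 and 3.27 ± 0.47 (SE, edgeR adjusted p = 6.39e-06 and 3.13e-05). TERF1 changed by -1.33 and 2.64 (edgeR adjusted p = 7.68e-08 and 4.07e-10). The difference between the RIPs was 6.29 for L1TD1 and 3.97 for TERF1 (edgeR adjusted p = 2.16e-09 and 9.3e-14). MEG3, an imprinted noncoding RNA, was at 0.409 ± 0.186 CPM (SD, n = 4) with ORF1p, 133.1 ± 30.3 CPM (SD, n = 4) with ORF2p and 139 ± 11.2 CPM (SD, n = 3) in the mock IP, and LINC-ROR fell by 6.01 on the log2 scale and DNMT3B, a DNA methyltransferase, by 4.16 with ORF1p (edgeR adjusted p = 1.34e-12, 3.76e-12 and 7.47e-12 for the ORF1p changes).

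In a minority of the pluripotency spans repeat reads rose with ORF1p, and in some of the noncoding RNA spans. Those within the span of NEAT1, the noncoding RNA of paraspeckles, rose by 2.63 ± 0.39 (SE), those of POU5F1, the pluripotency factor OCT4, by 3.17 ± 0.30 (SE) and those of PODXL, a surface glycoprotein, by 3.31 ± 0.25 (SE; edgeR adjusted p = 9.17e-06, 5.22e-08 and 3.02e-09). All 3 were lower with ORF2p than with ORF1p, at -3.0, -4.10 and -4.41 (edgeR adjusted p = 5.11e-07, 6.12e-10 and 2.16e-11). SNHG14, a long noncoding RNA that hosts small nucleolar RNAs, rose by 1.63 with ORF2p (edgeR adjusted p = 1.47e-08). Over 10431 genes, 4277 were higher and 1941 lower with ORF1p, and 1947 higher and 895 lower with ORF2p. The whole set was shifted, with the median span at 0.66 with ORF1p and -0.02 with ORF2p on the TMM scale, and at 0.56 and -0.33 with library totals, where 4039 were higher and 2034 lower with ORF1p and 1594 and 1859 with ORF2p. Spans of protein-coding genes gave 3490 higher and 1250 lower with ORF1p and 1217 and 727 with ORF2p, and those of long noncoding RNA genes 666 and 614 with ORF1p and 617 and 147 with ORF2p. Only repeat reads within a span were counted, so these values are no measure of the gene's mRNA.

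Total RNA of series bl differed from series b in 60 subfamilies higher and 100 lower, with L1HS at 1.27 and AluSx at -1.33 (edgeR adjusted p = 0.00714 and 1.49e-08).

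All 35 or 84 splits of the subfamily comparisons were run, or 100 drawn ones for the RIPs over total RNA. Splits other than the real one gave fewer calls in most comparisons, with only 1 split as large, the real one. That argues against a chance division of the libraries there. It cannot tell a group from a batch that goes with it. For subfamilies these were ORF1p RIP over mock IP (173 calls, the highest other split 97), ORF2p RIP over mock IP (88 and 11), ORF1p RIP over total RNA (187 and 60) and ORF2p over ORF1p RIP (203 and 1). For ORF2p RIP over total RNA, with 69 calls, 2 of 100 splits were as large. The other split, with 98 calls, set total RNA of series bl apart, so a division by series gave more calls than that by the RIP. The rank alone therefore does not show that these calls come from the RIP. Within the series the real split gave 89 higher and 30 lower over series b and 96 and 25 over series bl. For mock IP over total RNA, with 8 calls, chance cannot be excluded, since 9 of 84 splits were as large. The highest, with 79, set total RNA replicates 4 to 6 apart, all of series bl, which points to a structure of the samples.

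For young L1 loci 35 splits were run, or 40 drawn ones over total RNA, and for all loci and gene spans only 25 drawn ones. Among these only 1 split, the real one, was as large in each comparison. That argues against a chance division only as far as they were drawn, as no rank below 1 in 25 was possible with 25. The 41 young loci higher in mock IP over total RNA were 5 without mock IP replicate 2, so chance is not excluded there. The real and highest other values for young loci were 4825 and 3065, 6006 and 4, 5768 and 2715, 6626 and 5358, 41 and 4, and 1647 and 1, in the order ORF1p and ORF2p over mock IP, ORF1p and ORF2p over total RNA, mock IP over total RNA, and ORF2p over ORF1p. For ORF1p over mock IP, ORF2p over mock IP and ORF2p over ORF1p they were 23677 and 15287, 13838 and 124, and 23004 and 0 in all loci, and 6218 and 3535, 2842 and 391, and 5982 and 2 in gene spans.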
